A study of Mus musculus with 4 samples.

How the data were processed

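H3K27ac ChIP-seq of hippocampal layer tissue was measured in 4 samples from male B6CASTF1/J mice aged 2 months. The labels tie them to 2 tissue pools, C (biological replicate 1) and D (biological replicate 2), each made from 7 biosamples and sequenced as 2 technical replicates, with fragments of 200 to 600 bp. All 4 samples formed 1 group, and the pool was the unit of replication.

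The authors deposited 4 peak lists in narrowPeak format on build mm10, per the samples' descriptive text. That text gives a replicated list from both pools, a list from the alignments of both pools together, and a list from each pool with its technical replicates joined. It calls the last 3 pseudoreplicated, and each list derives from filtered alignments and from 2 further files whose kind it does not name. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal of each peak is the authors' own value, whose scaling is not given in the sources used here. The −log10 p and −log10 q values per peak were deposited by the authors in the columns the format reserves for them, and the summit is a distance from the peak start. Signals and p-values were used to describe, rank or filter peaks within a list, and between lists only for equal values at identical intervals and for rank correlations. No read totals were in the files used, so the depth per sample is unknown: a region without a peak is one not detected at this depth, and a difference between the pool lists can come from depth. Wilson intervals (95%) cover the counting of genes only.

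Chromosome lengths were checked against the GRCm38 genome sequence, and no peak of the 350032 in the 4 lists ended beyond its chromosome. Genes and transcription start sites (TSSs) came from GENCODE M21, with 21853 protein-coding genes. Strain differences from the C57BL/6 reference were not analysed here. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

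The groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Peaks of 2 lists were shared when at least 50% of the peak was overlapped, and signal ranks across shared peaks were described by Spearman's rho. A promoter peak lay within 1 kb of an annotated TSS. The promoter share was compared with 99 seeded shuffles of the peaks on their chromosomes. The 27 gene lists, of cell types, synapse and activity genes, other tissues and controls, were each compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Covered length was the number of bp in peaks within 10 kb of the main TSS, tested with 100000 random lists of the same size. Genes are not replicates, so these tests set lists against other genes in these pools. Broad domains were peaks stitched at up to 10 kb and ranked by the sum of signal times length, and a gene counted when its TSS lay in one of the first 500 domains or was nearest to it. Matches of 13 consensus motifs on both strands were counted in 500 bp windows and divided by those of 50 shuffled versions. The named genes were, per list, up to 4 members with the highest promoter signal and up to 2, in alphabetical order, with no promoter peak, then the genes of the 15 strongest peaks and of the 15 first domains. Any other gene in the text was named after its values were seen, among them further members given to complete a count, the Y-linked genes and the list members at broad domains. Some genes this rule takes are not reported here.

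Alternatives were peaks with a −log10 q of 5 or more, the stronger part of each list above the median signal, each other list in place of the replicated one, and each pool left out. Overlaps of 1 bp and of 50% in both directions were tried, with TSS windows of 500 bp and 2.5 kb, covered windows of 25 and 2 kb, stitching at 5 and 2.5 kb and the first 250 or 1000 domains. Further alternatives were motif windows at the summit or of 1 kb, and a background matched on transcript number (4 classes) and promoter CpG (5 classes). Chosen after seeing the data were motif shuffles with the same number of CG, and gene lists without members whose promoter peak also held a TSS of another coding gene.

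The Fisher test of lists, the covered length test, the promoter share and the motif scan were tested on simulated data, while the matched backgrounds, the differences between lists and the X ratios were not. The Fisher test called 0 of 100 random lists of 20 genes, and it called all 20 lists made of 19 genes with a promoter peak and 1 without and all 20 made of 3 with and 17 without. Within each set of 20 built lists the counts were the same, so each set amounts to 1 calculation and measures no sensitivity. The covered length test called 1 of 100 random lists and all 20 lists enriched for long coverage. With 10% of 88930 random peaks moved to TSSs, the promoter share was 16.2% against 16.2% planned. In 20000 random windows with 4000 planted AP-1 sites, the recovered ratio was 4.34 against 4.50 planned, and the other motifs lay between 0.556 and 2.68. No motif passed the adjustment there, the planted one included, so the motif test as planned cannot call a single motif.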

Results

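Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-seq in hippocampal layer tissue of male mice aged 2 months. The animals were F1 hybrids of the C57BL/6 and CAST strains. The 4 samples formed 1 group, from 2 tissue pools named C and D, each made from 7 biosamples and sequenced as 2 technical replicates. The design had no treated or untreated arm, so the questions it implies are where the mark lay, which genes and cell types carried it, and how far the pools matched. The data were 4 peak lists called on GRCm38 (mm10): a replicated list from both pools, a list from both pools together, and a list from each pool. Read totals per sample were not in the files used here, so the sequencing depth behind the peaks is unknown, and the intervals below cover the counting of genes or peaks only.

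The replicated list held 88930 peaks with a median width of 947 bp, which covered 119.0 Mb or 4.37% of the genome. Its widest peak spanned 40013 bp on chromosome 15 over Lncppara, a non-coding gene next to the let-7c-2 and let-7b microRNAs. It was picked after its value was seen. Peaks over 5 kb numbered 1921 in the replicated list, 1937 in the pool C list and 412 in the pool D list. Pool C gave 94836 peaks (median width 894 bp, 122.9 Mb) and pool D gave 63623 (743 bp, 64.5 Mb). The list from both pools together held 102643 peaks. Of the replicated peaks, 82099 (92.3%) had the same start and end there, and in each of these the signal was equal too, while the other 6831 overlapped none of its peaks. A −log10 q under 5 was listed for 12.2% of the replicated peaks.

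Regions marked in pool D were nearly all marked in pool C, while many weaker pool C regions were not in the pool D list. At an overlap of at least 50% of the peak, 96.0% of pool D peaks lay in pool C peaks and 32.5% of pool C peaks lay in pool D peaks. Promoter peaks were shared most: 99.02% of those in pool D and 60.8% of those in pool C were covered by the other pool. The share was 22.9% for pool C peaks in introns, 22.1% in exons and 30.8% between genes. It went from 4.57% in the weakest 10% of pool C peaks by signal to 81.3% in the strongest 10%. Part of the gap came from width: with any overlap counted, 50.9% of pool C peaks touched a pool D peak, and with a reciprocal overlap of 50%, 47.5% of pool D peaks had a partner in pool C. Across shared peaks the signal ranks had a Spearman rho of 0.895 from pool C to pool D and 0.720 from pool D to pool C, a description across peaks, which are not independent replicates.

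**Figure D1:**
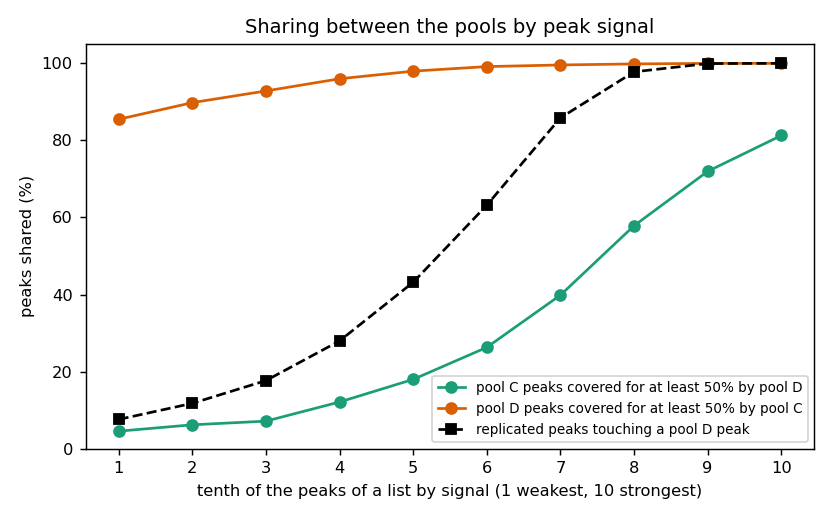
Share of peaks found in the other pool's list (vertical axis, %) by peak signal within each list (horizontal axis, 10 classes of equal size from weakest to strongest). Circles use an overlap of at least 50% of the peak and squares give replicated peaks that touch any pool D peak, and sharing from pool C to pool D goes from 4.57% to 81.3%.

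Of the replicated peaks, 48021 (54.0%) overlapped peaks of both pool lists, 26791 (30.1%) overlapped pool C peaks alone, 1332 (1.498%) overlapped pool D peaks alone and 12786 (14.4%) overlapped neither. Peaks in both pools were wide and strong, with a median of 1515 bp and a median signal of 6.36. Those in neither list had a median of 396 bp and a signal of 2.89. The signal of a peak is the authors' own value and was used to describe, rank or filter peaks within a list.

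Promoters were enriched among the marked regions. Within 1 kb of an annotated transcription start site (TSS) lay 19671 replicated peaks, 22.1% of the list, against 7.16% ± 0.086 (SD over 99 shuffles) for the same peaks placed at random on their chromosomes. This was 3.09-fold, with a permutation p of 0.01, the smallest that 99 shuffles can give. Introns held 51.5% of the peaks (1.28-fold), exons 5.21% (1.45-fold) and the space between genes 21.1% (0.432-fold), each with the same p. Promoter peaks were wider (median 1412 bp) and had a higher median signal (9.79) than intron peaks (871 bp, 3.81) and intergenic peaks (798 bp, 4.08). The promoter share was 21.1% in pool C and 29.7% in pool D.

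**Figure D2:**
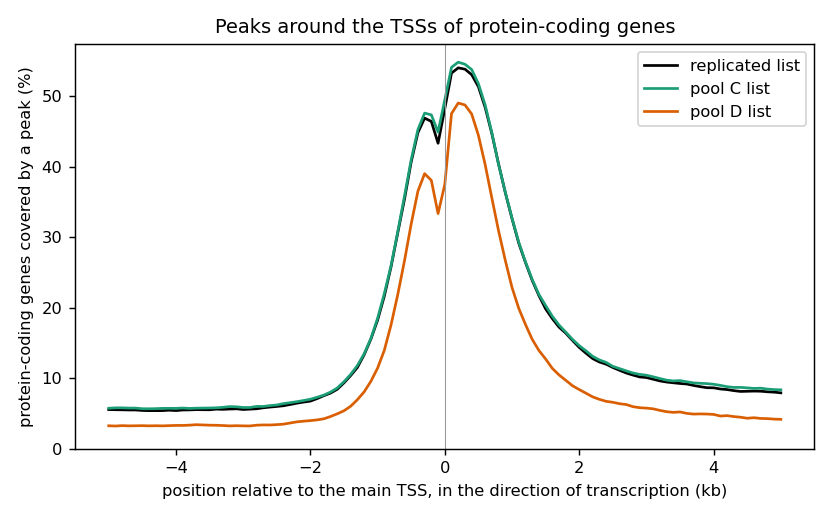
Share of protein-coding genes (vertical axis, %) with a peak at each position from 5 kb before to 5 kb after the main TSS (horizontal axis, kb, in the direction of transcription), for the replicated, pool C and pool D lists. Each curve dips just before the TSS and is highest after it, and the pool D curve lies below the others.

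A promoter peak was found at 13290 of 21853 protein-coding genes (60.8%, 95% Wilson interval 60.2 to 61.5%). The pool C list marked 13418 genes and the pool D list 12480. Both pools marked 12454 genes, pool C alone 964 and pool D alone 26. The highest signal of the replicated peaks, 51.5, was at chromosome 2, 128966093 to 128969026, over TSSs of Zc3h6 and Gm10762. Pcbp1, an RNA-binding protein gene, followed with 50.8, then 0610009B22Rik (49.5), Kmt5b, a histone H4 lysine 20 methyltransferase gene (48.8), and Mdm2, whose product is a ubiquitin ligase for p53 (48.7). The iron-sulfur scaffold gene Iscu shared its peak with Sart3 (47.6). Ywhaz, a 14-3-3 protein gene (46.5), Rhof with Setd1b (45.5), Vti1b (45.2), Cox20 (44.8), Zfp335 (44.3), Cenpo with Ptrhd1 (44.2) and Stam (44.1) were also among the 15 strongest. A further peak of the 15, at chromosome 19, 5794601 to 5809242, lay over the non-coding gene Malat1, which was named after its value was seen.

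The single X chromosome of these males carried few peaks. It held 7.77 peaks per Mb, while the 19 autosomes held between 29.2 and 51.8. A promoter peak was found at 412 of 948 X-linked genes (43.5%, Wilson interval 40.3 to 46.6%) and at 12874 of 20722 autosomal genes (62.1%), an odds ratio of 0.469 (two-sided Fisher's exact test, p = 8.2e-30). The odds ratio was 0.462 among genes with CpG-rich promoters (observed over expected CpG of 0.6 or more), at 83.9% against 91.8% (exact p = 4.3e-05), and 0.742 among the others, at 28.7% against 35.2% (exact p = 0.00047). On the Y chromosome, 5 peaks lay at the TSSs of Kdm5d, Eif2s3y, Uty and Ddx3y, the last with 2 of them.

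Markers of excitatory neurons carried the mark without exception. All 20 genes of that list had a promoter peak in the replicated list and in each pool list, against 60.8% of other genes (two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 27 lists, adjusted p = 0.0002). The strongest were at Gria2, an AMPA receptor subunit gene (signal 28.8, chromosome 3, 80797725 to 80803584), Bhlhe22 (24.9), Grin2b, an NMDA receptor subunit gene (23.0), and Arpp21 (22.8). The mark was also present at all 20 presynaptic genes, among them Vamp2 (38.0), Dnm1 (27.9) and Rab3a (23.6), and at all 21 postsynaptic genes, among them Ppp1r9b (30.8), Homer1 (29.7), Camk2b (25.8) and Dlgap1 (24.8), each with an adjusted p of 0.0002. It was present at all 20 forebrain transcription factor genes (exact adjusted p = 0.0002), among them Mef2a (38.3), Zeb2 (34.4) and Tcf4 (24.96). The lists overlap, so their calls are not independent. Camk2a and Nrgn are in both the excitatory and the postsynaptic list, and Mef2c is in the excitatory and the forebrain list. Gria1, Gria2, Grin2a and Grin2b are in the excitatory and the glutamate receptor list, and Homer1 is in the immediate early and the postsynaptic list. Sox10 is in the oligodendrocyte and the oligodendrocyte precursor list. Neurod1 is in the neurogenesis and the forebrain list, and Grik4 in the pyramidal cell and the glutamate receptor list.

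Dentate granule cell markers were marked at 15 of 16 genes (exact adjusted p = 0.0126), led by Rfx3 (signal 41.3), Stxbp6 (19.5), C1ql3 (17.3) and Dock10 (16.8), and Pdia5 had a peak in pool C alone. Markers of pyramidal cells of the CA fields were marked at 14 of 16, which missed the threshold (exact adjusted p = 0.0506). Among these Grik4 (17.7), Amigo2 (15.3), Man1a (11.4) and Wfs1 (10.4) had the highest signals, and Iyd and Map3k15 had no promoter peak. All 24 genes of the immediate early list, which holds genes that respond to neuronal activity, carried a peak (exact adjusted p = 5.3e-05). Nr4a3 (37.1), Homer1 (29.7), Fosl2 (25.5) and Junb (24.6) led them. Glutamate receptor genes were marked at 19 of 22 (exact adjusted p = 0.0211), with Grin1 at 26.9 and Grik5 at 23.6, while Grik1, Grm4 and Grm8 lacked a replicated peak. GABA receptor genes were marked at 14 of 17 (exact adjusted p = 0.107). Gabra2 (29.98) and Gabrb2 (24.5) were among the strongest of these, and the cerebellar subunit gene Gabra6 and the genes Gabrr1 and Gabrr2 had none.

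GABA interneuron markers were marked at 11 of 22 genes (50%, Wilson interval 30.7 to 69.3%, exact adjusted p = 0.43). Among the peaks above the median signal the share was 31.8%, which passed as below other genes (exact adjusted p = 0.0245). Cnr1 (14.9), Gad1 (12.4), Kcnc2 (8.91) and Sox6 (8.78) had the highest signals. Calb2 and Dlx1 were among those with no replicated promoter peak, and Dlx1 had a peak in pool C alone. Sst, Pvalb and Vip, named here after their values were seen, also had no replicated promoter peak. Markers of newborn neurons and neural stem cells were marked at 9 of 15 (exact adjusted p = 1), with Neurod1 (16.0), Sox4 (14.6) and Tubb3 (12.9) but not Draxin or Eomes.

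Glial and vascular lists were each set against other genes. All 20 astrocyte genes carried a promoter peak (exact adjusted p = 0.0002), among them the glutamate transporter gene Slc1a2 (25.2), Clu (19.4), the glutamine synthetase gene Glul (19.3) and Ndrg2 (18.7). So did all 20 oligodendrocyte genes (exact adjusted p = 0.0002), with lower signals at Mbp, the myelin basic protein gene (14.2), Enpp2 (10.97), Cnp (10.8) and Tspan2 (8.06). Oligodendrocyte precursor genes were marked at 8 of 12 (exact adjusted p = 0.837), with Tnr (21.8), Olig1 (8.47), Vcan (6.48) and Olig2 (6.13) and without C1ql1 or Lhfpl3. Microglia genes were marked at 13 of 20 (exact adjusted p = 0.852), with Sall1 (13.7), Csf1r (6.82) and P2ry12 (6.25) and without C1qa or C1qb. Of the genes named here without a replicated peak, Lhfpl3, C1qa and C1qb had a promoter peak in pool C alone. Endothelial and mural cell genes were marked at 15 of 20 (exact adjusted p = 0.298), with Slc2a1 (24.1), Pdgfrb (8.91), Vtn (7.81) and Sox18 (6.90) and without Abcb1a or Abcc9. Choroid plexus and ependymal genes were marked at 5 of 12 (exact adjusted p = 0.29), namely Foxj1 (11.1), Ttr (6.09), Dynlrb2 (5.01), Kl (4.97) and Rarres2, while Aqp1 and Ccdc153 were not. The pools differed in several lists: pool C marked 17 microglia genes and pool D 7, oligodendrocyte precursor genes came to 10 and 5, oligodendrocyte genes to 20 and 16, endothelial and mural genes to 15 and 11, and interneuron genes to 14 and 8. The share of pool C genes that pool D lacked lay within the 95% range of gene sets matched on pool C promoter signal for each of these 5 lists, with microglia at its upper limit (64.7%) and interneuron genes at its median (42.9%). Astrocyte and excitatory neuron genes came to 20 in each pool. In the pool D list alone oligodendrocyte genes missed the threshold (adjusted p = 0.0603, Fisher's exact test), and microglia genes passed it in the pool C list (adjusted p = 0.0495) and in the list from both pools together (adjusted p = 0.0499).

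**Figure D3:**
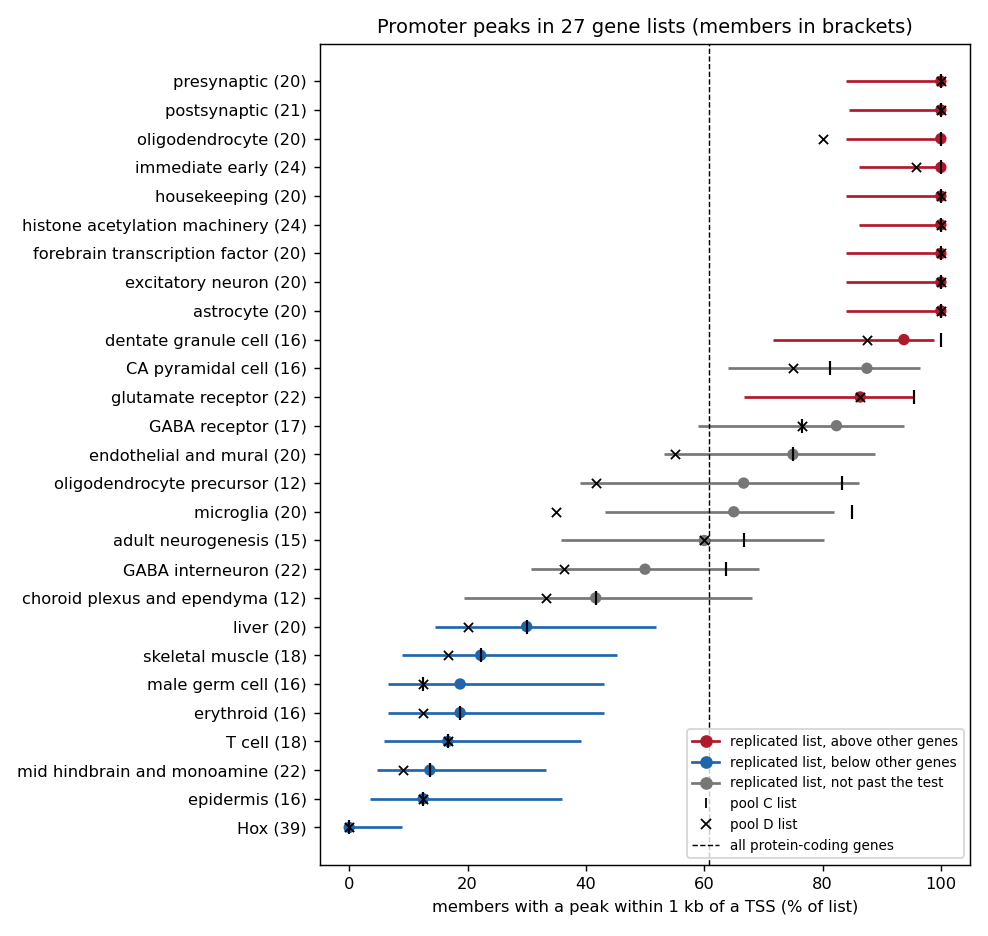
Share of the members of 27 gene lists with a peak within 1 kb of a TSS (horizontal axis, %), with the number of members in brackets, for the replicated list (dots, with 95% Wilson intervals), pool C (vertical ticks) and pool D (crosses). The dashed line gives all protein-coding genes (60.8%), and excitatory neuron, astrocyte and oligodendrocyte lists lie at 100% and Hox genes at 0% in the replicated list.

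Genes of other tissues and body regions lacked the mark for the most part. None of 39 Hox genes, which pattern the trunk and hindbrain, had a promoter peak in the replicated or either pool list (Wilson interval up to 8.97%, exact adjusted p = 3.5e-15). Mid- and hindbrain and monoamine neuron genes were marked at 3 of 22, namely Dbh (8.67), Ddc (4.74) and Gata2 (4.51), and not at Atoh1 or Barhl1 (exact adjusted p = 5.3e-05). T cell genes were marked at 3 of 18 (exact adjusted p = 0.000605): Bcl11b (19.8), which is also on the forebrain list, Foxp3 (13.5) and Tcf7 (5.90), but not Cd2 or Cd28. Epidermis genes were marked at 2 of 16, Krt10 (19.8) and Trp63 (5.46), and not at Cdsn or Dsc3 (exact adjusted p = 0.000218). Erythroid genes were marked at 3 of 16, among them Epor (7.10) and Klf1 (5.21), and not at Alas2 or Epb42 (exact adjusted p = 0.00191). Male germ cell genes were marked at 3 of 16, Dazl (7.87), Spata16 (6.48) and Zpbp (6.47), and not at Acr or Ddx4 (exact adjusted p = 0.00191). Spata16 had a promoter peak in neither pool list. Skeletal muscle genes were marked at 4 of 18, Mylpf (13.4), Actn3 (12.95), Casq1 (5.32) and Tnni2 (3.24), and not at Acta1 or Atp2a1 (exact adjusted p = 0.00191). Liver genes were marked at 6 of 20, with Apoh (20.6), Foxa3 (13.2), Fga (8.56) and Ttr (6.09) and without Ahsg or Alb (exact adjusted p = 0.0144). Ttr is also on the choroid plexus and ependymal list. With a TSS window of 2.5 kb the muscle genes missed the threshold (exact adjusted p = 0.0687). Some of these peaks also held a TSS of another protein-coding gene, as at Apoh (Prkca), Foxa3 (Sympk), Mylpf (Tbc1d10b), Actn3 (Zdhhc24) and Foxp3 (Ppp1r3f). All 20 housekeeping genes (Ywhaz at 46.5 and Actb at 43.6 among the strongest, exact adjusted p = 0.0002) and all 24 genes of the histone acetylation machinery (Brd2 at 43.0, Ep300 at 39.0, Hdac2 at 37.2 and Kat6b at 35.2 leading, adjusted p = 5.3e-05) carried the mark.

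Genes differ in transcript number and in the CpG content of their promoters, and random lists matched on both were a second background. Against these the mark stayed more frequent at oligodendrocyte genes (100% against 55.7% in the matched lists, permutation test, adjusted p = 9e-05), astrocyte genes (66.9% in the matched lists, adjusted p = 0.000675), postsynaptic genes (74.4%, adjusted p = 0.0157), excitatory neuron genes (72.9%, adjusted p = 0.0182) and presynaptic genes (81.8%, adjusted p = 0.0417). Microglia genes (65.0% against 38.5%, permutation adjusted p = 0.0191) and GABA receptor genes (82.4% against 56.7%, adjusted p = 0.0382) passed the test with this background and not against all other genes. Of the 20 microglia genes, the pool C list marked 17 and the pool D list 7, a share below the matched 38.5%, and this background was not run for each pool. Hox genes (74.8% in the matched lists) and mid- and hindbrain genes (71.3%) stayed below, both with a permutation adjusted p of 9e-05, the smallest reached, as did male germ cell genes (52.1%, adjusted p = 0.00886). The calls ended for forebrain transcription factor genes (89.4% in the matched lists, permutation adjusted p = 0.152), immediate early genes (86.6%, adjusted p = 0.0717), dentate granule cell genes (73.8%, adjusted p = 0.0516), glutamate receptor genes (72.3%, adjusted p = 0.108), housekeeping genes (85.6%, adjusted p = 0.0951) and histone acetylation genes (86.0%, adjusted p = 0.071). They ended too for liver genes (31.6% in the matched lists) and erythroid genes (20.9%), each with a permutation adjusted p of 1, and for epidermis genes (29.96%, adjusted p = 0.124), muscle genes (41.2%, adjusted p = 0.108) and T cell genes (39.0%, adjusted p = 0.0516).

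Covered length separated the lists further, because it does not saturate as promoter presence does. The background matched on transcript number and promoter CpG was not run for covered length or for the broad domains. Forebrain transcription factor genes had the most: 11312 bp ± 6309 (SD over 20 genes) of the 20 kb around the main TSS lay in replicated peaks, against a mean of 2276 bp in random lists of the same size. Zeb2 was covered over 16939 bp. Excitatory neuron genes followed with 9220 bp ± 4688 (n = 20 genes), postsynaptic genes with 8120 bp ± 5124 (n = 21), presynaptic genes with 7535 bp ± 3801 (n = 20), immediate early genes with 7023 bp ± 4098 (n = 24), astrocyte genes with 6907 bp ± 3473 (n = 20), dentate granule cell genes with 6305 bp ± 4600 (n = 16), oligodendrocyte genes with 6152 bp ± 3187 (n = 20) and glutamate receptor genes with 5714 bp ± 4306 (n = 22). In the permutation test with 100000 random lists, two-sided, each of these reached p = 1e-05, the smallest it can give, and an adjusted p of 3e-05. Housekeeping genes, marked at every promoter, had 5324 bp ± 3115 (n = 20, adjusted p = 4.9e-05). Histone acetylation genes had 4248 bp ± 3063 (n = 24, adjusted p = 0.00297) and oligodendrocyte precursor genes 4032 bp ± 3333 (n = 12, adjusted p = 0.0449). In the pool D list these means were lower and their order changed. Oligodendrocyte genes had 2864 bp there, below housekeeping (3870 bp) and histone acetylation genes (3047 bp), and astrocyte genes had 4402 bp. The call for precursor genes ended in the pool D list (1759 bp, adjusted p = 0.738, permutation test), among the peaks above the median signal (adjusted p = 0.348) and with windows of 25 kb (adjusted p = 0.399) or 2 kb (adjusted p = 0.4), and that for histone acetylation genes at 25 kb (adjusted p = 0.0861).

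Below the random lists were Hox genes with 0 bp (n = 39, adjusted p = 4.9e-05), mid- and hindbrain genes with 560 bp ± 1611 (n = 22, adjusted p = 0.0113), erythroid genes with 615 bp ± 1766 (n = 16, adjusted p = 0.0353), male germ cell genes with 719 bp ± 1010 (n = 16, adjusted p = 0.0449) and epidermis genes with 746 bp ± 1610 (n = 16, adjusted p = 0.0449), each by the permutation test. In the pool D list the male germ cell genes (500.1 bp) and the epidermis genes (499.4 bp) missed the threshold, with a permutation adjusted p of 0.0677 for both. Among the peaks above the median signal the erythroid (permutation adjusted p = 0.0561), epidermis (0.0653) and male germ cell genes (0.0654) missed it, and male germ cell genes did at 25 kb (0.154). The remaining lists did not pass in the main setting. They were GABA receptor genes (3618 bp ± 2882, permutation adjusted p = 0.0645), endothelial and mural genes (3497 bp ± 3473, adjusted p = 0.0688), CA pyramidal cell genes (2899 bp ± 1876, adjusted p = 0.401), microglia genes (2713 bp ± 3063, adjusted p = 0.506), neurogenesis genes (2515 bp ± 2960, adjusted p = 0.741), interneuron genes (1606 bp ± 2109, adjusted p = 0.318), muscle genes (1588 bp ± 2175, adjusted p = 0.345), T cell genes (1532 bp ± 4007, adjusted p = 0.318), choroid plexus and ependymal genes (1490 bp ± 2207, adjusted p = 0.371) and liver genes (1085 bp ± 1323, adjusted p = 0.0728). Of these, endothelial and mural genes passed in the pool C list (permutation adjusted p = 0.0357) and the list from both pools together (0.0444), and GABA receptor genes in the pool C list (0.0411) and at 2 kb (0.0208). At 2 kb the liver (permutation adjusted p = 0.03), muscle (0.0221) and T cell genes (0.00427) passed as below the random lists.

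**Figure D4:**
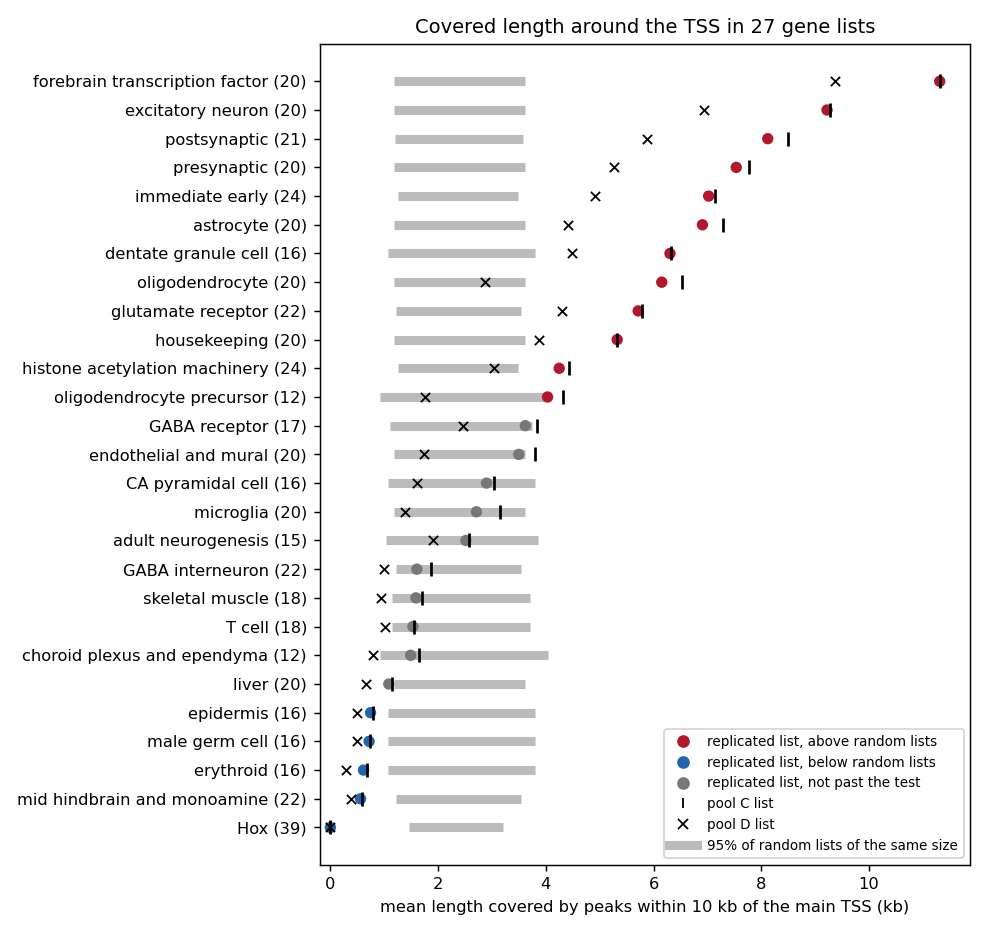
Mean length covered by peaks within 10 kb of the main TSS (horizontal axis, kb) for 27 gene lists, with members in brackets, for the replicated list (dots), pool C (vertical ticks), pool D (crosses) and the range that holds 95% of random lists of the same size (grey bars). Forebrain transcription factor genes lie highest at 11312 bp, and Hox genes lie at 0 bp.

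Broad domains of the mark were frequent at forebrain transcription factor, excitatory neuron and postsynaptic genes. Stitching peaks at most 10 kb apart gave 32474 domains, and the 500 with the highest sum of signal times length had a median length of 67898 bp, held 19.01% of the peak length and lay at 1005 protein-coding genes. A domain can rank high through its length, and the gene lists were not matched on gene length. The first was at Tcf4, a basic helix-loop-helix transcription factor gene (chromosome 18, 69342268 to 69693648), where 94 peaks covered 86.3% of 351381 bp, and pool C covered 87.6% and pool D 62.7%. Next in rank came Msra (chromosome 14, 338520 bp), Celf2, an RNA-binding protein gene (chromosome 2, 498276 bp), and Gria1, an AMPA receptor subunit gene (chromosome 11, 325172 bp). The fifth domain (chromosome 15, 85625283 to 85710224) had Ppara as the nearest coding gene and held the non-coding Lncppara with the microRNA genes Mirlet7c-2 and Mirlet7b. The sixth (chromosome 2, 30640046 to 30836780) held coding TSSs of 1700001O22Rik, Asb6, Ntmt1 and Prrx2 and the non-coding genes 4930527E20Rik, 9330198N18Rik, Gm14486, Gm14488 and Mir3089, of which all but 1700001O22Rik were named after the values were seen. The others of the first 15 were at Zbtb20, Nfix, Zbtb16, Thra, Zeb2, Ttc7b, Kalrn, Grin2a and Celf4. Their lengths ran from 108149 bp at Thra to 303746 bp at Grin2a.

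Forebrain transcription factor genes were at a top domain in 13 of 20 cases, against 4.54% of other genes (two-sided Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 5.9e-12). Excitatory neuron genes were there in 10 of 20 (exact adjusted p = 6.6e-08), among them Camk2a, Gria1, Grin2b and Neurod2, and postsynaptic genes in 10 of 21 (adjusted p = 8.1e-08), among them Dlg4 and Ppp1r9b. Some domains were assigned by the nearest TSS: those ranked 14 (Grin2a), 19 (Mef2c, on the forebrain and excitatory lists) and 38 (Grin2b) held no coding TSS. Immediate early genes were there in 6 of 24 (Btg2, Fosb, Junb, Nr4a1, Nr4a3 and Per1, exact adjusted p = 0.00415), presynaptic genes in 5 of 20 (Bsn, Cplx2, Dnm1, Rab3a and Vamp2, adjusted p = 0.00957) and dentate granule cell genes in 4 of 16 (Maml2, Prox1, Rfx3 and Stxbp6, adjusted p = 0.0234). Per1 and Vamp2 lay in the same domain (rank 68), so the immediate early and presynaptic calls are not independent. Glutamate receptor genes (4 of 22, exact adjusted p = 0.0647), housekeeping genes (3 of 20, adjusted p = 0.208) and astrocyte genes (2 of 20, adjusted p = 0.702) did not pass. The 4 glutamate receptor genes are all on the excitatory list too. The call for dentate granule cell genes held in neither pool list alone (exact adjusted p = 0.132 in pool C and 0.408 in pool D), nor at a −log10 q of 5 or more (0.537), above the median signal (0.439), with stitching at 2.5 kb (0.22) or among the first 250 (adjusted p = 1) or 1000 domains (0.125). That for immediate early genes ended among the first 250 domains (exact adjusted p = 0.0867) and with peaks stitched at 2.5 kb (adjusted p = 0.0943). Glutamate receptor genes passed with stitching at 2.5 kb (exact adjusted p = 0.000115) or 5 kb (0.00246), in pool D (0.00634) and among the first 1000 domains (0.0279). Housekeeping genes passed above the median signal (exact adjusted p = 0.00061), in pool D (0.0233), with stitching at 5 kb (0.0129) and among the first 1000 domains (0.000567). None of the CA pyramidal cell, interneuron, microglia or Hox genes lay at a top domain. Of the 500 domains, 457 (91.4%) overlapped one of the first 500 domains of pool C and 390 (78.0%) one of pool D.

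**Figure D5:**
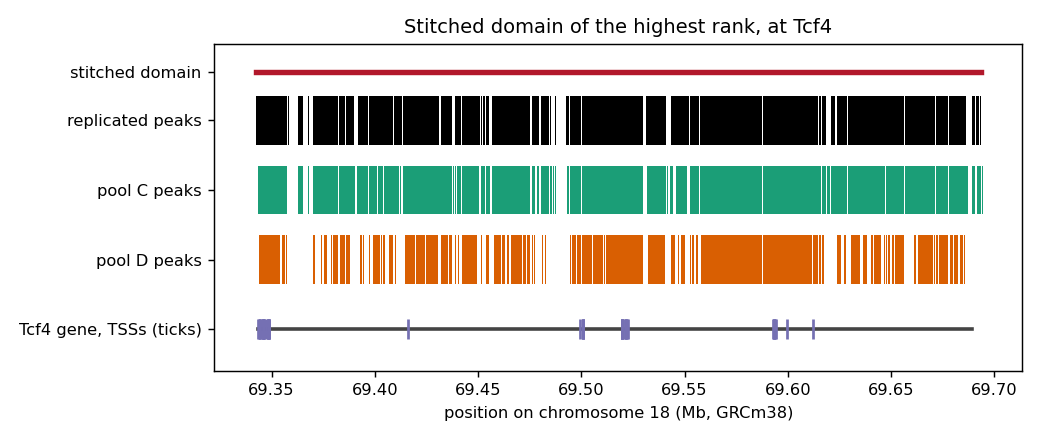
Map of the domain of the highest rank at Tcf4 (horizontal axis, position on chromosome 18 in Mb, GRCm38). Bars give the peaks of the replicated, pool C and pool D lists, the red line the stitched domain and ticks the coding TSSs of Tcf4, and pool C peaks cover 87.6% of the domain and pool D peaks 62.7%.

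Motifs of brain and other transcription factors were counted in the 69259 replicated peaks over 1 kb from any TSS, in the 500 bp around the midpoint and in windows 3 kb to each side. The central windows had 46.0% GC and the flanks 44.5%. The motif of RFX factors had 53 central matches against a mean of 14.5 in the flanks, and its ratio was 3.55 times that of 50 shuffled versions of its consensus (two-sided permutation p = 0.0196, the smallest possible, adjusted p = 0.255). The E-box of NEUROD factors had 7224 matches against 5252.5, or 1.27 times the shuffled ratio (permutation p = 0.0392, adjusted p = 0.255). MEF2 had fewer central matches than flanking ones, 6592 against 6939, at 1.27 times the ratio of its shuffled versions, and AP-1 had 7856 against 6331.5, at 1.248 times, both with a permutation p of 0.0784. The ratios over shuffled versions were 1.39 for PU.1, 1.21 for NFI, 1.18 for CTCF, 1.14 for CRE, 1.12 for EGR and 1.06 for ETS, and 0.962 for SOX, 0.954 for GATA and 0.927 for the liver factor HNF4A. None of the 13 motifs passed the Benjamini-Hochberg adjustment, and with 50 shuffled versions a motif can pass only if at least 6 of the 13 reach the smallest p, so these values describe the windows and exclude no motif. With windows of 1 kb the CTCF ratio was 1.80 (permutation adjusted p = 0.127).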

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

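The tests of this part on the X chromosome per gene, on peaks near the calling threshold, on single glial lists left out and on doubled signal minimums were chosen only after the result was seen. The list from both pools together held 20544 peaks (20.0%) that overlapped no replicated peak, a signal in a list the main comparisons do not use, with a median signal of 2.89 and a median width of 434 bp.

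Of 61 oligodendrocyte, precursor, microglia, endothelial and mural genes with a promoter peak in pool C, 24 (39.3%) had none in pool D, which may reflect lower sensitivity in pool D or a smaller share of these cells there. Gene sets matched on pool C promoter signal lost a median of 29.5% (95% range 21.3 to 37.7%), so the bound set before this test, a loss above that range, was met against sensitivity alone. That bound was wrong, because the 4 lists were joined after their losses were seen, and none of 26 lists with a pool C peak lay above its own matched range. In a rule added after the first value was known, each list was left out in turn: the loss stayed above the range without endothelial and mural genes (43.5%, upper limit 41.3%), reached its upper limit without oligodendrocyte genes (47.6%) or precursor genes (36.5%), and lay within it without microglia genes (29.5%, range 13.6 to 31.8%, the 92.5th percentile of matched sets). Sensitivity and cell share cannot be told apart with 1 list per pool, and since all samples form 1 group no biological explanation was tested by a contrast of groups.

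The X chromosome had 7.77 peaks per Mb against 35.6 on the autosomes. Gene number as the whole cause is argued against by 1.40 peaks per coding gene on X, below the lowest autosome at 2.73. A halved read depth as the whole cause is argued against by a test with its bound set beforehand. X peaks with a −log10 p of 10 or more had 0.442 times the autosomal density at 20 or more, where at least 0.8 was needed. The densities are per Mb, and X held 5.54 coding genes per Mb against 8.41 on the autosomes. The test therefore cannot decide whether depth was part of the cause. That test takes −log10 p to grow with depth, and a version with doubled signal minimums, tried after this value was seen, gave 0.564, 0.792 and 1.40 at minimums of 2.5, 5 and 10, so how the signal scales limits it. Depth together with gene number stays open, at 0.671 per gene in the replicated list, 0.765 in pool C and 0.851 in pool D, and no biological explanation was tested.

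Replicated peaks absent from the pool D list may lie near the calling threshold. Of the strongest 10% by signal, 0.0112% touched no pool D peak, and of the weakest 10% the share was 92.4%. At all 82099 intervals shared with the list from both pools together, the replicated signal equalled the signal there. Pool D therefore takes part in this ranking, and the pattern is partly built in. Depth and yield of pool D stay open behind this, since no read totals were used, and no biological explanation was tested.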

How the results depend on the processing

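The shuffled motifs with equal CG number and the lists without shared promoter peaks were chosen only after the result was seen. Of the alternatives for the summary values, 95 stayed within the limits set and 25 moved. The limits were unlike: a fixed ratio to the main value for counts and the narrow main Wilson interval for shared peaks. For width and rho it was the SD of the 2 pool values, and for promoter enrichment and the X odds ratio the side of the test. The 2 totals therefore do not measure 1 tolerance. Among single lists and motifs, 661 kept their side of the threshold, 20 passed only in the alternative and 33 passed only in the main setting. Of those that passed in the main setting, 0 turned direction. Turns were not counted for the others, and some did turn: ETS went from 1.06 to 0.972 with shuffles of equal CG number. Of the 661, 39 were for motifs, whose test cannot call a single motif, so these show no stability. Where not given by construction, the cause was not tested. By construction, median width was 1067 bp at a −log10 q of 5 or more and 1539 bp in the 44517 peaks of the stronger part of the list, and without each pool in turn it was 743 to 894 bp. With an overlap of 1 bp, pool C held 84.1% and pool D 55.5% of replicated peaks, 50.9% of pool C peaks were in pool D and 97.2% of pool D peaks in pool C. With reciprocal overlap, pool C held 75.8% of replicated peaks, 31.9% of pool C peaks were in pool D, 47.5% of pool D peaks in pool C, and rho from pool D to pool C was 0.903. In the stronger part these shares were 98.3% for pool C, 61.9% for pool D, 99.9551% for the list from both pools, 55.3% of pool C in pool D and 99.7% of pool D in pool C. The matched background left 7 lists above and 3 below for promoters (main 11 and 8). Lists below for covered length (main 5) were 2 in the stronger part, 8 at 2 kb and 3 to 5 with a pool left out. Genes at top domains (main 1005) were 576 with stitching at 2.5 kb, 526 at 250 domains and 1796 at 1000. Promoter enrichment and the X odds ratio kept their side in each setting. Motif tests passed in none. Unknown depth limits every statement on absent peaks. No paired analysis was possible because all samples belong to 1 group.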

Other observations

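All tests in this part were chosen only after the result was seen, and the gene families were picked by hand. Chemosensory receptor families were nearly free of the mark: 7 of 1134 olfactory receptor genes (0.617%, Wilson interval 0.299 to 1.27%) had a promoter peak, as did 2 of 331 vomeronasal receptor genes (two-sided Fisher's exact test, adjusted p = 3.5e-131 over 12 families) and 0 of 35 bitter taste receptor genes (interval up to 9.89%, adjusted p = 1.7e-14). The clustered protocadherins, adhesion proteins of neurons, were also below other genes, with 3 of 14 in the alpha (exact adjusted p = 0.00499), 1 of 22 in the beta (adjusted p = 5.8e-08) and 4 of 21 in the gamma cluster (adjusted p = 0.000191). These small counts differed between pools C and D: 12 and 2 for olfactory receptors, 3 and 1 for the alpha, 0 and 0 for the beta and 7 and 3 for the gamma cluster. Keratin genes had 6 of 53 (exact adjusted p = 2.1e-13). Above other genes were ribosomal proteins with 76 of 79 (exact adjusted p = 7.4e-13), subunits of mitochondrial complex I with 36 of 36 (adjusted p = 4.2e-08), zinc finger genes named Zfp with 336 of 394 (adjusted p = 5.1e-26) and the histone cluster on chromosome 13 with 42 of 54 (adjusted p = 0.0124). Voltage-gated potassium channels Kcna to Kcnd had 14 of 17, which did not pass (exact adjusted p = 0.0829). Near-identical copies can lose reads that map to several places, and whether such reads were kept is not given in the sources used here.

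Among non-coding genes, a promoter peak was found at 1246 of 5854 long intergenic RNA genes (21.3%), 1276 of 2959 antisense genes (43.1%), 483 of 2202 microRNA genes (21.9%) and 395 of 9940 processed pseudogenes (3.97%), a share that includes peaks of neighbouring coding genes. Wide single peaks lay at Bcl11a (27556 bp), Mical2 (26001 bp) and Zeb2 (25192 bp), and one of 31169 bp on chromosome 13, from 83712688 to 83743856, held C130071C03Rik and Mir9-2. The summit of the strongest peak within 1 kb of the main TSS lay a median of 166 bp downstream over 12683 genes, and downstream in 70.4% of them.

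Dentate granule cell genes had more covered length than CA pyramidal cell genes, at 6305 bp ± 4600 (SD, n = 16) against 2899 bp ± 1876 (n = 16), a difference of 3406 bp (two-sided permutation test, p = 0.010, adjusted p = 0.010 over 2 comparisons). It was 3285 bp in pool C (permutation p = 0.0132) and 2879 bp in pool D (p = 0.00432). Excitatory neuron genes had 7614 bp more than interneuron genes (n = 20 and 22, p = 2e-05, the smallest this test can give, adjusted p = 4e-05). The lists are markers picked by hand and hold no measure of cell number.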
